A study of Mus musculus with 15 samples.

How the data were processed

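Messenger RNA was sequenced in 15 libraries, 3 in each of 5 groups. Per the labels, the cells were MDA-MB-468, an established line from a basal-like breast carcinoma. They had received a control hairpin (NC), either of 2 short hairpin RNAs against SHCBP1, or either of 2 against TMEM45A. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, fragmented and copied with random primers using a NEBNext Ultra kit, and sequenced as paired ends. This kit does not mark the strand, so reads from a gene and from an antisense or overlapping neighbour cannot be told apart.

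The authors deposited 2 tables of counts, whole numbers of reads per gene symbol with no normalization, each with 58735 rows. The table with NC also holds the shSHCBP1 libraries, and the other table holds the shTMEM45A libraries alone. The aligner and the counting program are not given in the sources used here. The submitters' processing notes name the mouse build mm10 and the labels give the mouse as organism, whereas the tables carry human gene symbols. They were treated as human counts, and the build behind them stays open. Coordinates were not used here, because the reference genome at hand was that of the mouse. Names that stood on more than 1 row, or that a spreadsheet had turned into dates, were left out: 200 names on 1768 rows, which left 56967. SOD2 is among them. Every library column of both tables was used.

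Column names gave the library for 12 columns. The shTMEM45A columns are numbered 2 and 4, while the labels number these sets 1 and 2. The columns numbered 2 were taken as the labels' set 2, and those numbered 4 as the remaining set by elimination. The sets are called set 2 and set 4 here after the columns, and which of the 2 stated hairpin sequences each carries is open. The columns of set 4 end in 1, 2 and 3, but these digits could not be tied to the labelled libraries. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

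Genes were kept with filterByExpr (count minimum 10, total minimum 15), which left 19051. Library sizes were scaled by TMM, and all 15 libraries entered a single fit of group means with edgeR 4.0.16 in R 4.3.3. Each comparison used the quasi-likelihood F test with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values for genes come from that test. Standard errors (SE) of log2 fold changes were taken as the size of the change divided by the square root of F. Levels are TMM-scaled CPM, counts relative to the scaled library total, given as mean ± SD of 3 libraries. The comparisons were each hairpin set against NC, the mean of both sets of a target against NC, set against set within a target, and the mean of both shTMEM45A sets against the mean of both shSHCBP1 sets. Gene lists, 27 in all, covered pathways, complexes and other cell types. They were tested on log2 CPM (prior count 2) with camera from limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and their p-values were adjusted over the lists. The lists, the tests, the naming rule and the main set of alternatives were fixed before the data were examined.

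Named genes followed a rule. It takes both targets, and the 10 largest rises and 10 largest falls of each target among genes past the threshold in both sets in the same direction. It also takes up to 2 rises and 2 falls per list, and 5 in each direction for the remaining comparisons. Outside the lists, a mean log2 CPM of at least 2 was required, and clone-type names and pseudogenes were left out. Genes outside the rule are said to have been chosen after their values were seen.

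Comparisons against the same NC libraries share chance values, so unchanged groups were simulated 20 times against those controls. NC has 3 libraries and could not be split into parts of at least 2, so part of any excess over the simulated value may come from the shared controls. The pipeline was tested on simulated data for shSHCBP1_1 against NC over 19051 genes. Changes were put into 100 genes per size, all at 2 CPM or more in NC. It recovered 70% of the genes changed 1.5-fold and 86% of those changed 2-fold, with 7 false calls. Recovery at lower levels was not tested, and far fewer genes were changed than passed in the real comparisons with NC. In 10 simulations of the mean of both shSHCBP1 sets against NC over 19051 genes, camera found a list changed 1.2-fold in 10. It called 0 of 260 unchanged lists. These lists were random genes drawn independently of each other, so false calls of lists whose members move together were not tested.

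Library totals ran from 13780294 to 16484000 counts. At this depth 3 counts correspond to at most 0.218 CPM. A gene at 0 counts in a group was set to 3 counts over that group for a bound, and a gene with 1 to 3 counts is given as a ratio with an exact 95% interval. Intervals and bounds cover counting error only. No replicate pair was alike within counting noise: the chi-square per gene was 1.74 to 2.99 between NC or shSHCBP1 replicates and 3.65 to 9.15 between shTMEM45A replicates, over genes with at least 20 counts in the pair. Alternatives were DESeq2's size factors (RLE), the DESeq2 1.42.0 Wald test, no low-count filter, a stricter filter of 1 CPM, a fit of only the groups compared, the replicate number as a block, and each library left out in turn. Scaling by total counts and by the upper quartile, and a block that numbers set 4 by its column names, were added after the data were seen.

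Transcript length was read from mouse transcripts of the same symbol, the longest per gene, from GENCODE. It was found for 67.3% of all genes tested, too few for a check over all of them. Among the 12705 genes with a mean log2 CPM of at least 2 it was found for 84.6%, and only those 10750 genes were used for trends, a choice made after the data were seen. For a gene list, length was used only where at least 80% of the members had one.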

Results

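The series compared cells carrying hairpins against SHCBP1 or TMEM45A with cells carrying a control hairpin. Its title places these genes in a prognosis model built on disulfidptosis, a form of cell death tied to disulfide stress under glucose shortage. SHCBP1 is an SHC-binding protein active in dividing cells, and TMEM45A is a transmembrane protein. Each of the 5 groups held 3 libraries. Totals ran from 14123463 to 14400254 counts in NC, from 14040356 to 16257001 in shSHCBP1_1 and from 13780294 to 14092177 in shSHCBP1_2. They ran from 14754541 to 16484000 in shTMEM45A set 4 and from 15620787 to 15891057 in set 2. The first principal component took 75.6% of the variance and separated the shTMEM45A libraries from all others. Of 28 basal keratin and squamous genes, only 4 had enough counts to be tested, although the labels name a basal-like breast line.

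The knockdowns were checked first in the targeted transcripts. SHCBP1 stood at 44.1 ± 2.53 CPM in NC (SD, n = 3), at 47.1 ± 1.25 in shSHCBP1_1 and at 44.3 ± 1.12 in shSHCBP1_2. Its log2 changes were 0.10 (SE 0.07, edgeR adjusted p = 0.412) and 0.01 (SE 0.07, adjusted p = 0.962), so the transcript was not detectably lower in either set. Those 6 libraries are therefore called the libraries labelled shSHCBP1. In the shTMEM45A libraries SHCBP1 was higher, at 52.4 ± 1.62 CPM in set 4 and 59.9 ± 6.55 in set 2 (adjusted p = 0.00355 and 3.7e-06), although the rise in set 4 no longer passed under total-count scaling (log2 change 0.06). TMEM45A stood at 26.6 ± 2.09 CPM in NC and fell by 0.58 on the log2 scale in set 4 (17.8 ± 1.86 CPM, adjusted p = 8.8e-06) and by 0.46 in set 2 (19.4 ± 0.761 CPM, adjusted p = 0.000182). In the libraries labelled shSHCBP1_1 and shSHCBP1_2 it stood at 28.3 ± 2.86 and 24.4 ± 1.35 CPM, with adjusted p = 0.579 and 0.356. The shTMEM45A sets stand in another table than NC, and 7402 and 7580 of 19051 genes passed as lower in sets 4 and 2. The fall of TMEM45A alone therefore does not show a knockdown.

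**Figure D1:**
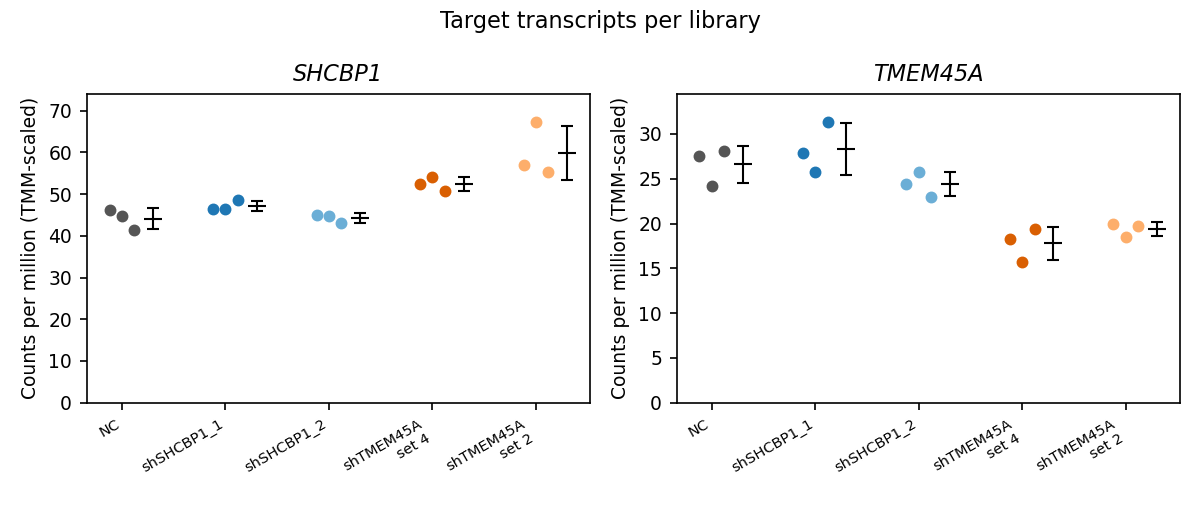
SHCBP1 and TMEM45A in each library, in TMM-scaled CPM; points are libraries, and the black mark and bar beside them are the mean and SD of 3. SHCBP1 averages 44.1 in NC against 47.1 and 44.3 in the libraries labelled shSHCBP1, while TMEM45A averages 26.6 in NC against 17.8 and 19.4 in the shTMEM45A sets.

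What changed in the libraries labelled shSHCBP1 was asked next, against NC. With pseudogenes and genes under a mean log2 CPM of 2 left out, DHRS2, a short-chain dehydrogenase, rose most, from 4.31 ± 0.306 CPM in NC to 29.9 ± 1.39 in shSHCBP1_1 and 53 ± 2.87 in shSHCBP1_2, a mean log2 change of 3.21 (SE 0.09). CHAC1, a glutathione-degrading enzyme of the integrated stress response, rose by 2.73 (SE 0.18), HES5, a Notch target, by 1.97 (SE 0.31), and the heat shock gene HSPA6 by 1.87 (SE 0.34). The zinc finger gene ZNF543, the mitochondrial sirtuin SIRT4, FAM200A, METTL18, KRCC1 and LRIF1 rose by 1.42 to 1.68. Among the falls, XIST, a non-coding RNA, went from 4864 ± 188 CPM to 2190 ± 8.36 and 1843 ± 68.3, a change of -1.28 (SE 0.04). The collagen gene COL14A1 changed by -1.04 (SE 0.06) and IRF7, a transcription factor of the interferon response, by -1.02 (SE 0.19).

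The other large falls were CDHR5 (-1.33), ARHGAP8 (-1.12), LINC00893 (-1.03), LRP1B (-0.99) and the monocarboxylate carrier SLC16A4 (-0.95). RN7SL2, part of the signal recognition particle RNA family (-1.51), shares sequence with near-identical copies and is uncertain, as is XIST, whose antisense partner cannot be separated without strand. Over 19051 genes, 3787 passed in shSHCBP1_1 (1779 higher, 2008 lower) and 5921 in shSHCBP1_2 (2980 higher, 2941 lower), but only 325 and 741 of them changed more than 2-fold. A fit of only NC and the libraries labelled shSHCBP1 called 6078 in shSHCBP1_1. The direction of small changes depended on scaling: 47.0% of calls in shSHCBP1_1 and 50.3% in shSHCBP1_2 were higher with TMM, against 29.1% and 34.6% with RLE and 86.1% and 81.7% with total counts.

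Genes of several basic cell functions fell in these libraries, by the mean of both sets. The 10 most abundant genes of a library took 6.88% of counts in NC, 5.80% in shSHCBP1_1 and 5.56% in shSHCBP1_2. Whether the changes follow the level of a gene was not tested, so the falls may not be particular to these functions. Chance is not excluded for the number of lists called: 9 of 100 splits of these libraries, the real one included, gave at least 10. Each list below that is called lower or higher passed camera, with its adjusted p in the sentence. All 27 cytosolic ribosomal protein genes tested fell, 27 also adjusted over the list alone (adjusted p = 3.2e-20), and the list median was negative under all 4 scalings. RPL7A fell by 0.51 and RPL3 by 0.49. Ribosomal protein genes took 10.2% ± 0.161 of counts in NC, 9.18% ± 0.147 in shSHCBP1_1 and 8.64% ± 0.0943 in shSHCBP1_2. Of 28 oxidative phosphorylation genes, 23 fell and 0 rose, 24 adjusted over the list alone (adjusted p = 1.1e-10); examples were ATP5F1B (-0.43), a subunit of ATP synthase, and NDUFV2 (-0.68), a complex I subunit, whose fall no longer passed without NC replicate 2 (log2 change -0.57). Of 27 sterol and fatty acid synthesis genes, 19 fell and 1 rose, in both counts (adjusted p = 1.0e-07), among them HMGCS1 (-0.71, SE 0.05), of the mevalonate pathway, and CYP51A1 (-0.69), a sterol demethylase. Under total-count scaling both lists still passed camera, but 9 oxidative phosphorylation genes fell and 1 rose (median -0.07 against -0.23), and 13 sterol and fatty acid genes fell and 5 rose.

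Of 30 glycolysis and hypoxia genes, 21 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 1.0e-07); P4HA1, a collagen prolyl hydroxylase, changed by -0.80 and GAPDH by -0.55. The actin and WAVE complex genes tied to disulfidptosis had 14 of 20 lower and 1 higher, in both counts (adjusted p = 6.0e-06), with filamin A, FLNA (-0.70), and talin, TLN1 (-0.60), falling most, and CD2AP higher by 0.29. Of 22 mesenchymal and matrix genes, 11 fell and 1 rose, or 12 and 3 adjusted over the list alone (adjusted p = 0.0023), with fibronectin, FN1, at -0.93 (SE 0.06) and the collagen cross-linking enzyme LOX at -0.58, while SNAI2, a repressor of epithelial genes, rose by 0.57. Total-count scaling left these 3 lists past camera, with 13 lower and 4 higher glycolysis and hypoxia genes, 9 and 5 actin and WAVE complex genes, and 9 and 4 mesenchymal and matrix genes. DNA replication genes had 12 of 30 lower and 3 higher, or 14 and 4 adjusted over the list alone (adjusted p = 0.0134), with RRM2, a ribonucleotide reductase subunit, at -0.63 and GINS3 at 0.49. By single set, this list passed camera in shSHCBP1_1 (adjusted p = 0.000495) but not in shSHCBP1_2 (adjusted p = 0.136). The list median turned from -0.11 to 0.04 under total-count scaling and the call of the list was lost (adjusted p = 0.54).

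Endoplasmic reticulum chaperone genes had 8 of 20 lower and 2 higher, in both counts (adjusted p = 0.0023), but adjusted p = 0.162 with an estimated correlation, and the list median turned from -0.11 to 0.05 under total-count scaling. HSPA5, the main chaperone of that compartment, fell from 9724 ± 110 CPM to 6340 ± 90.3 and 5989 ± 57.0, and HSP90B1 changed by -0.60. Higher lists were p53-pathway and CDK inhibitor genes, 8 of 22 higher and 1 lower, or 9 and 1 adjusted over the list alone (adjusted p = 0.00625), and NF-kB target genes, 5 of 19 higher and 0 lower, or 4 and 0 (adjusted p = 0.0076). SESN2, a stress-induced regulator of mTORC1, rose by 0.85 and TP53INP1 by 0.75, while CCNG1 fell by 0.45 on the log2 scale. RELB, an NF-kB subunit, rose by 1.03 (SE 0.14). TNF had 3 counts in NC against 13 and 34, ratios of 3.77 (95% interval 1.04 to 20.6) and 10.4 (3.27 to 52.9), and its call was lost without NC replicate 1. The NF-kB list median was 0.58 as fitted and 0.22 with CXCL8 and CXCL10, which were at 0 counts in a group, set to their bound. Of the 10 lists that passed, the other 9 also passed with an estimated correlation.

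Both hairpin sets against SHCBP1 were compared gene by gene. In the same direction, 3382 genes passed in both (1582 higher, 1800 lower) and 2 passed in opposite directions; independent lists of these sizes would share 278 higher and 310 lower. Fold changes correlated across genes, which are not independent replicates, with r = 0.83, against 0.50 in simulations of unchanged groups that shared the controls. Their covariance was 0.221 against a simulated 0.0533. Simulations gave 0 genes called in both, which follows from changing no gene and sets no chance level for the 3382. The numbers for independent lists leave out the shared controls. With only NC and these libraries in the fit, 5297 genes passed in both.

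**Figure D2:**
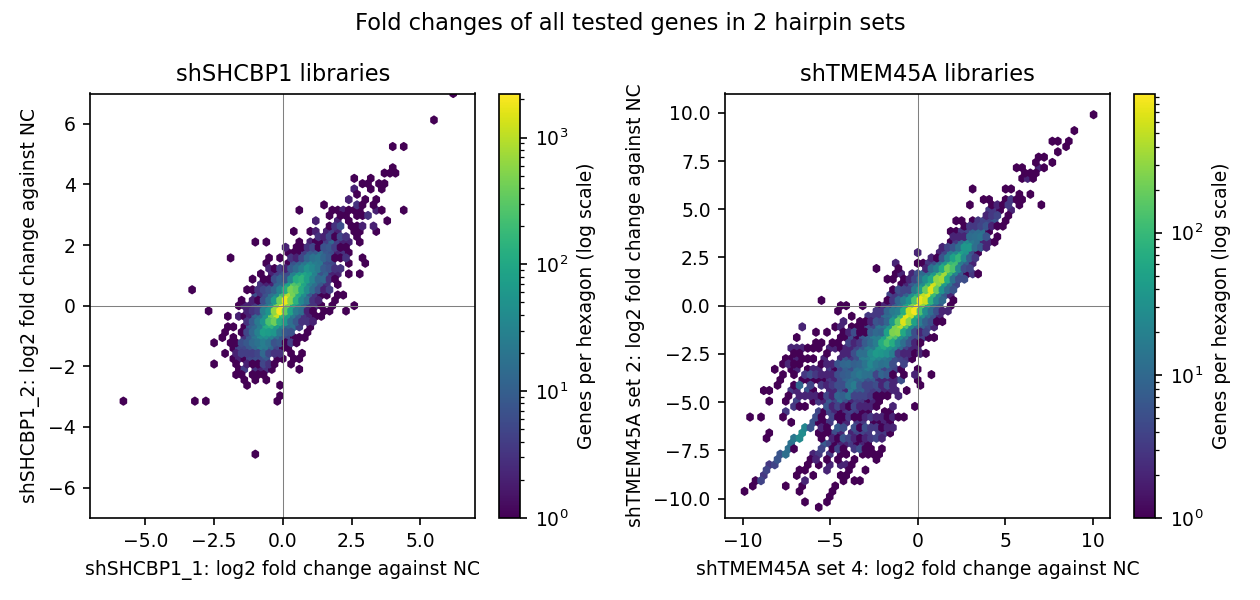
Log2 fold change against NC of all 19051 genes tested in 2 hairpin sets of the same target; colour gives the number of genes per hexagon on a log scale. The clouds lie along the diagonal, with r = 0.83 for the libraries labelled shSHCBP1 and 0.93 for shTMEM45A, where changes are several times larger.

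The same question was asked of the shTMEM45A libraries. NC was counted only in the other table, so target and table cannot be told apart in any comparison with NC. Among the largest rises were the interferon-stimulated genes ISG15, IFIT1, IFIT2, IFIT3 and OASL, although IRF9 and USP18 of the same list fell. ISG15, a ubiquitin-like interferon-induced protein, went from 4.96 ± 0.935 CPM in NC to 184.2 ± 16.2 in set 4 and 183.7 ± 10.5 in set 2, a mean log2 change of 5.21 (SE 0.10). IFIT1, which binds foreign RNA, rose by 5.15 (SE 0.12), IFIT3 by 5.81 (SE 0.20) and IFIT2 by 7.92 (SE 0.24). OASL had 3 counts in NC against 1116 and 1029, ratios of 388.6 (95% interval 132.6 to 1887) and 354.8 (121.1 to 1723). The chemokine gene CCL5 had 3 counts in NC against 3711 and 3361, ratios of 1292 (442 to 6268) and 1159 (396 to 5623). DHRS2 rose by 4.36 (SE 0.09), to 72.8 ± 1.57 and 107.9 ± 3.91 CPM, and the non-coding RNA MAFG-DT by 3.79. MAFA-AS1 (3.69) is an antisense gene, uncertain because the reads carry no strand.

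Among the falls, XIST dropped from 4864 ± 188 CPM to 34.2 ± 3.62 in set 4 and 26.5 ± 2.0 in set 2, a mean change of -7.34 (SE 0.04). CYP51A1 had 512 counts in NC and 0 in set 2, at least 165-fold lower, and stood at 0.221 ± 0.149 CPM in set 4. EIF4A1, a translation initiation helicase, went from 110.6 ± 1.78 CPM to 2.43 and 1.88 (-5.69, SE 0.10), and SEC24C, a COPII coat protein, from 52.0 ± 1.69 to 1.53 and 0.834 (-5.50, SE 0.13). The cyclin gene CCNK (-6.08), the helicase gene DDX47 (-5.93), TMEFF1 (-5.74), SLC16A8 (-5.30) and LRRC7 (-5.27) fell to well under 1 CPM in both sets. NC stands in the other table and the counting program is not given, so all these falls may come from the target or from the table. JMJD7-PLA2G4B (-5.57) is a readthrough gene that overlaps its neighbours, so its value is uncertain. So is the rise of BOLA2B (4.63, SE 0.96), which has a near-identical copy and owes its size to replicate 1 of set 2, at 211.7 CPM against 6.06 to 12.2 in the other 5 shTMEM45A libraries; without it the change was 2.87.

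In all, 14176 genes passed in set 4 (6774 higher, 7402 lower) and 14460 in set 2 (6880 higher, 7580 lower), of which 7373 and 7931 changed more than 2-fold. Both sets shared 13117 genes in the same direction (6217 higher, 6900 lower) and 6 in opposite directions, where independent lists would share 2446 higher and 2945 lower. Across genes r was 0.93 against a simulated 0.52, and the covariance was 2.82 against 0.0532. Simulations gave 0 genes called in both, again because no gene was changed in them. The numbers for independent lists again leave out the shared controls.

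By list, 8 passed camera for the mean of the shTMEM45A sets, and none of them passed with an estimated correlation, where the lowest adjusted p was 0.0936. Counts adjusted over the list alone were equal to those over all genes in every list of this comparison. Interferon and double-stranded RNA response genes had 19 of 27 higher and 6 lower (adjusted p = 0.0104, and adjusted p = 0.0936 with an estimated correlation). The falling members were not minor: IRF9, part of the complex that turns interferon genes on, changed by -3.25 (SE 0.28), and USP18, which removes ISG15 from proteins, by -1.72 (SE 0.12). NF-kB target genes had 12 of 19 higher and 3 lower (adjusted p = 0.0393, and adjusted p = 0.0936 with an estimated correlation), and the call was lost under the stricter filter (adjusted p = 0.082). CXCL10, a chemokine induced by interferon, had 0 counts in NC against 193 and 178, at least 67.2- and 61.4-fold higher. The list median, 0.69, was the same with such genes set to their bound. IRAK2 changed by -0.81.

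All 27 ribosomal protein genes rose (adjusted p = 8.5e-12, and adjusted p = 0.0936 with an estimated correlation), led by RPS9 (1.72) and RPL37A (1.68), and the median was positive under all 4 scalings. They took 19.9% ± 0.271 of counts in set 4 and 19.8% ± 0.205 in set 2, against 10.2% in NC. Oxidative phosphorylation genes had 22 of 28 higher and 5 lower (adjusted p = 1.8e-05, and adjusted p = 0.123 with an estimated correlation). NDUFA1 and NDUFB3, small subunits of complex I, rose by 2.38 and 2.15, while NDUFV2 changed by -2.12 and ATP5F1B by -0.62. Sterol and fatty acid genes had 18 of 27 lower and 7 higher (adjusted p = 0.0211, and adjusted p = 0.0936 with an estimated correlation). HMGCS1 fell from 196.3 ± 8.17 CPM to 23.1 ± 1.66 and 11.3 ± 1.05, whereas NSDHL and MVK of the same pathway rose by 1.44 and 0.96. Mesenchymal and matrix genes had 18 of 22 lower and 2 higher (adjusted p = 0.00458, and adjusted p = 0.0936 with an estimated correlation), with FN1 at -2.80 (SE 0.06) and ITGB3, which had 34 counts in NC against 0 and 2, at least 10.9-fold lower in set 4. SNAI2 and vimentin, VIM, rose by 1.90 and 0.88. The medians of the sterol and matrix lists were the same with genes at 0 counts set to their bound.

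Glycolysis and hypoxia genes had 22 of 30 lower and 6 higher (adjusted p = 0.0104, and adjusted p = 0.0936 with an estimated correlation): ALDOA changed by -2.58 and PFKFB3 by -1.57, while the hypoxia-induced genes ANGPTL4 and CA9 rose by 2.09 and 1.69. Homologous recombination and damage response genes had 15 of 21 lower and 4 higher (adjusted p = 0.0211, and adjusted p = 0.146 with an estimated correlation), with RAD54B at -2.07, RAD54L at -2.01 and XRCC3 at 1.30. The disulfidptosis lists did not pass. The actin and WAVE complex genes had 13 of 20 lower and 6 higher (adjusted p = 0.0937), with TLN1 at -1.98 and MYL6 at 1.86, and the cystine, glucose and mitochondrial genes had 5 of 10 in each direction (adjusted p = 0.940), with SLC3A2, a partner of the cystine carrier, at 1.54 and NCKAP1 at -1.21.

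**Figure D3:**
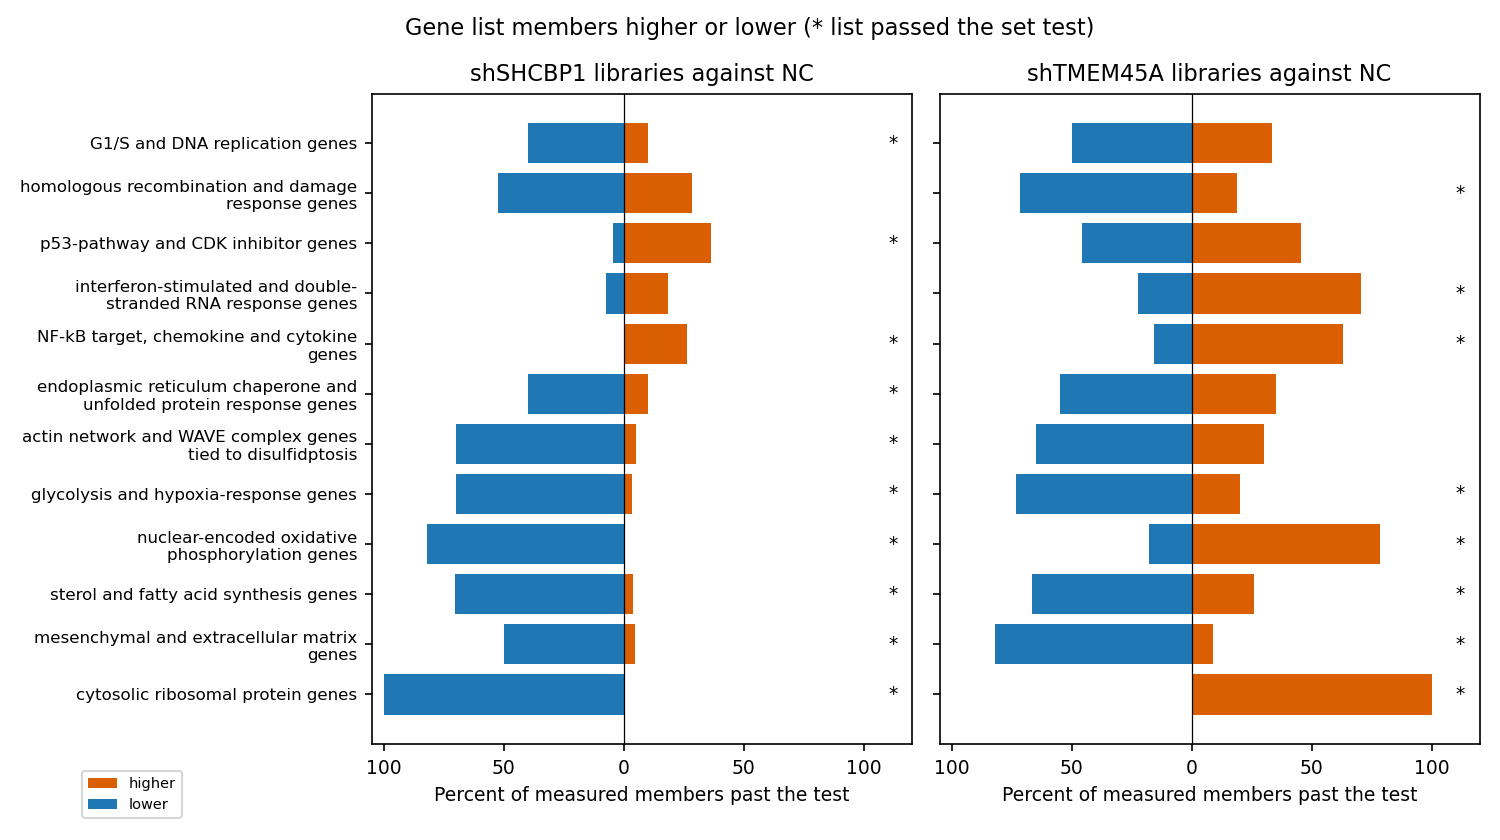
Percent of measured members of 12 gene lists that passed the test higher (right) or lower (left) against NC, for the mean of both hairpin sets of each target; an asterisk marks lists that passed camera with the preset correlation. Ribosomal protein genes are 27 of 27 lower in the libraries labelled shSHCBP1 and 27 of 27 higher in the shTMEM45A libraries.

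Fold changes in the shTMEM45A libraries moved with transcript length. Among 10750 genes, the 2150 shortest (median 1522 nt) had a median log2 change of 0.77, with 75.4% higher and 14.5% lower, and the 2150 longest (median 7010 nt) one of -0.69, with 11.6% higher and 76.2% lower. Across genes, Spearman's rho between length and log2 change was -0.51, against -0.05 in the libraries labelled shSHCBP1. Ribosomal protein genes had a median length of 1106 nt, and their median change was 1.18 before and 0.11 after a smooth length trend was subtracted. For the 23 of 28 oxidative phosphorylation genes with a length, median 1232 nt, these medians were 1.40 and 0.17. The damage response list, at 4645 nt, went from -0.82 to -0.35, the sterol list from -0.63 to -0.43 over members with a length, the matrix list from -0.89 to -0.69 and the glycolysis list from -0.50 to -0.48. NF-kB target genes went from 0.68 to 0.99, and the 23 of 27 interferon genes with a length from 1.62 to 0.82.

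**Figure D4:**
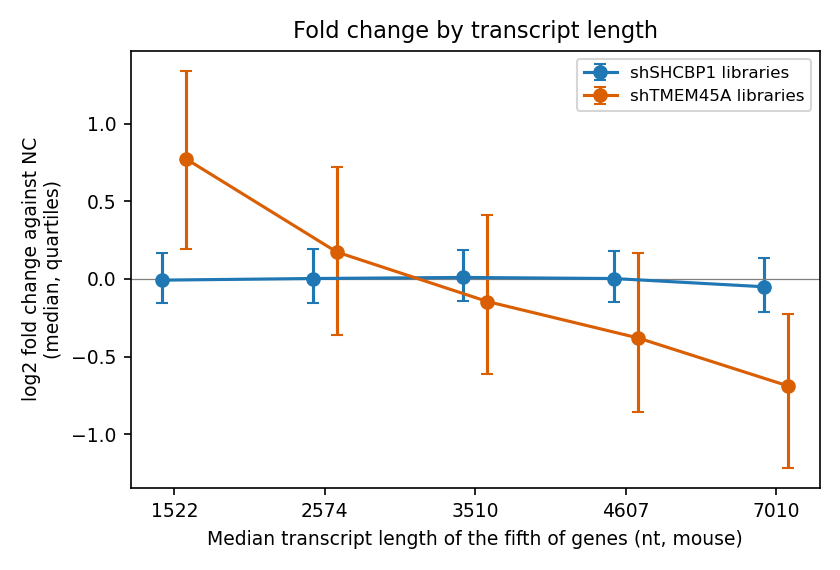
Median log2 fold change against NC in 5 groups of 10750 genes by transcript length, labelled by each group's median length in nt from the mouse gene of the same symbol; bars span the quartiles. The shTMEM45A median goes from 0.77 in the shortest group to -0.69 in the longest, and the shSHCBP1 median from -0.01 to -0.05.

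**Figure D5:**
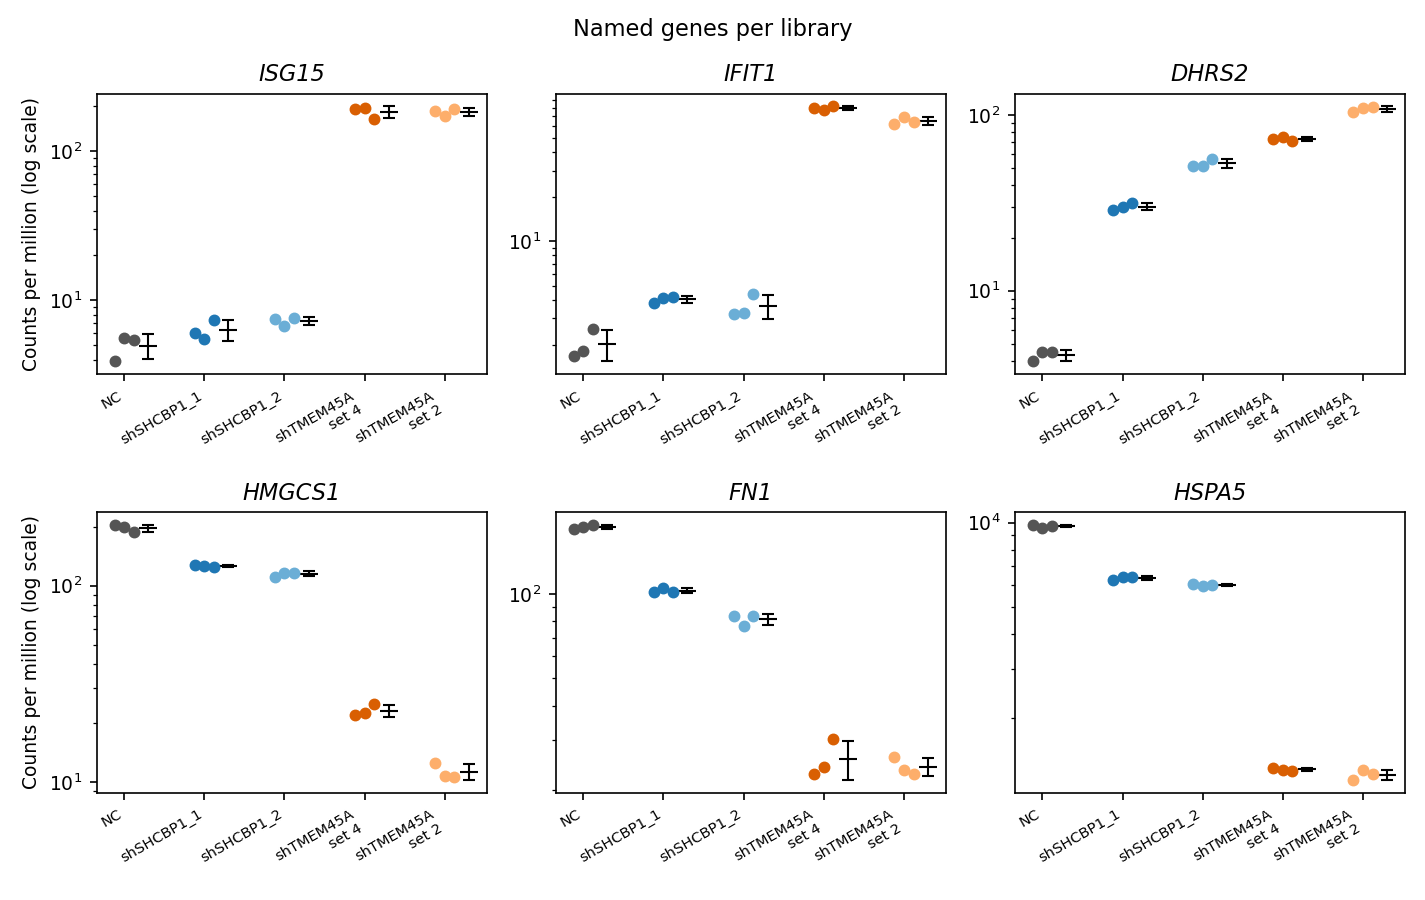
CPM of 6 named genes in each library on a log axis; points are libraries, and the mark and bar beside them are the mean and SD of 3. ISG15 averages 4.96 CPM in NC against 184.2 and 183.7 in the shTMEM45A sets, and HSPA5 averages 9724 in NC, 6340 and 5989 in the libraries labelled shSHCBP1, and 1308 and 1251 in the shTMEM45A sets.

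Both targets were also compared directly, again across tables. CCL5 was higher in the shTMEM45A libraries by 9.32 (SE 0.13), OASL by 6.20 (SE 0.19), IFIT2 by 6.0 (SE 0.14) and IFIT3 by 5.19 (SE 0.13). RN7SL2, uncertain for its copies, was higher by 5.10. Lower in the shTMEM45A libraries were CYP51A1, at 7.13 ± 0.474 and 7.58 ± 0.477 CPM in the libraries labelled shSHCBP1, XIST (-6.06, SE 0.04), CCNK (-5.97, SE 0.17), TMEFF1 (-5.55, SE 0.29) and DDX47 (-5.17, SE 0.22). In all, 15105 genes differed, 6697 higher and 8408 lower; 44.3% of calls were higher with TMM and 29.7% with total-count scaling. Against NC, 4252 genes changed in the same direction in the means of both targets, 2096 higher and 2156 lower, and 1022 in opposite directions. Independent lists, which leave out the shared controls, would share 1078 higher and 1254 lower. Simulations, with no gene changed, gave 0. Across genes r was 0.55, below the 0.68 of simulated unchanged groups, while the covariance was 0.468 against a simulated 0.0535. DHRS2 and CHAC1 (2.68 in the shTMEM45A mean) were higher, and XIST, HMGCS1, FN1 and HSPA5 (-2.93) lower, in both.

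Set against set within a target, the libraries stand in the same table. In shSHCBP1_2 the stress genes HSPA6 (1.26, SE 0.29) and HSPA1A (0.82, SE 0.12), as well as DHRS2 (0.82, SE 0.07) and CHAC1 (0.67, SE 0.15), were higher than in shSHCBP1_1, and the metallothionein gene MT2A was lower (-0.41, SE 0.08). In all, 159 genes differed, 95 higher and 64 lower in shSHCBP1_2; leaving out any of the 6 libraries brought this to between 27 and 54, and a fit of NC and these libraries alone called 1217. Of the named genes, DHRS2 and HSPA1A passed in each of those fits, and HSPA6, CHAC1 and MT2A each lost the call in at least 4 of the 6.

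Between the shTMEM45A sets 1004 genes differed, 372 higher and 632 lower in set 2, in the fit that shares a single estimate of the spread over all 15 libraries. A fit with NC and these libraries alone called 351. Replicates differed more in the shTMEM45A sets (chi-square per gene 3.65 to 9.15) than in the other groups (1.74 to 2.99), so 1004 may be too many. HSPA6 was higher in set 2 (9.90 ± 1.38 against 4.37 ± 1.0 CPM, adjusted p = 0.00361) and RAVER1, an RNA-binding protein, lower (2.20 ± 0.467 against 5.04 ± 0.863 CPM, adjusted p = 6.3e-05), as was STPG3 (-2.82, SE 0.56). SHCBP1 (adjusted p = 0.127) and TMEM45A itself (log2 difference 0.12, adjusted p = 0.556) did not pass between the sets.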

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

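The splits of libraries reported here were planned before the data were examined. What drew attention is that hairpin sets aimed at the same gene, in the same table, differed from each other in a test of the difference itself.

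Between the sets against SHCBP1, 159 genes differed. Higher in shSHCBP1_2 were HSPA6 (log2 difference 1.26), GPR89B (0.97), DHRS2 (0.82), HSPA1A (0.82) and CHAC1 (0.67); lower were STAG3L1 (-1.01), NOMO3 (-0.97), ZSCAN16-AS1 (-0.55), STAG3L2 (-0.50) and MT2A (-0.41). GPR89B, STAG3L1, STAG3L2 and NOMO3 have near-identical copies and ZSCAN16-AS1 is an antisense gene, so their values are uncertain. In a fit of these 6 libraries alone the real grouping gave 1617 genes and the highest of the other splits 2; with 10 splits, of which 1 was as large, the share cannot fall under 0.05.

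Between the shTMEM45A sets, 1004 genes differed. Higher in set 2 were BOLA2B (3.04), SERF1B (2.19), HSPA6 (1.18), the mitochondrial tRNA gene MT-TH (1.17) and UBL7-AS1 (1.14); lower were CYP51A1 (-4.75 as fitted), STPG3 (-2.82), DDX47 (-2.26), the cadherin gene DCHS1 (-1.23) and RAVER1 (-1.19). CYP51A1 had 9 counts in set 4 and 0 in set 2, at least 3.03-fold lower. BOLA2B rested on replicate 1 of set 2, and SERF1B on replicate 2 of set 2, without which its difference was 0.01; both have near-identical copies. UBL7-AS1 is an antisense gene and uncertain for want of strand. A fit of these 6 libraries alone gave 178 genes for the real grouping and 4 for the highest other split; 1 of 10 splits was as large, which is too few splits for a share under 0.05.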

How the results depend on the processing

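Scaling by total counts and by the upper quartile, and the block with set 4 numbered by its column names, were alternatives chosen after the data were seen. The counts of genes for each hairpin set against NC stayed within 1.5 times under every alternative, except that a fit of NC and the libraries labelled shSHCBP1 alone gave 6078 for shSHCBP1_1, against 3787. That fit also gave 5297 genes changed the same way in both of these sets, against 3382, and 1217 between them, against 159; the DESeq2 Wald test gave 425 between them. The fit of NC and the shTMEM45A libraries alone gave 351 genes between the shTMEM45A sets, against 1004. Lists called for the shTMEM45A libraries were 8, 16 with no low-count filter and 0 with an estimated correlation. The causes were not tested. The main fit shares a single estimate of the spread, while replicates differed more in the shTMEM45A sets (chi-square per gene 3.65 to 9.15) than in the others (1.74 to 2.99). This goes with the larger counts for SHCBP1 and the smaller ones for shTMEM45A in the fits of fewer groups. Leaving out each library in turn gave 27 to 54 genes between the sets against SHCBP1, the lowest without shSHCBP1_1 replicate 1; fewer libraries enter those fits. BOLA2B between the shTMEM45A sets turned from 3.04 to -0.48 without shTMEM45A set 2 replicate 1 (adjusted p = 0.223), and went to 3.59 without shTMEM45A set 2 replicate 2.

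Leaving out a library gave 2655 to 2796 genes for shSHCBP1_1, 4605 to 4892 for shSHCBP1_2, 13609 to 13948 for shTMEM45A set 4 and 14008 to 14551 for set 2. Genes shared by both sets were 2400 to 2907 for SHCBP1 and 12577 to 13306 for TMEM45A; genes between the shTMEM45A sets were 706 to 1306, and those between targets 15066 to 15473. Of 104 named genes called in the mean of the libraries labelled shSHCBP1, 25 lost the call under an alternative set in advance, 24 of them when a library was left out; of 116 for shTMEM45A, 2 did. Between sets, 8 of 10 and 7 of 10 did, and between targets 0 of 10. Total-count scaling moved the median log2 change of all genes to 0.16 in the mean of the libraries labelled shSHCBP1 and to -0.24 in that of shTMEM45A, from 0.01 and -0.05.

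The replicate numbers did not pair the libraries: 18 same-numbered pairs had correlations of deviations from -0.035 to 0.038, and 6 of 12 libraries correlated best with their own number. With the replicate block, 3652 genes passed for shSHCBP1_1, 5790 for shSHCBP1_2, 14368 for shTMEM45A set 2, 3283 in both sets against SHCBP1 and 158 between them, and 11 lists passed for SHCBP1. These fits left set 4 without a number. With the replicate block and set 4 numbered by the last digit of its column names, 14069 genes passed for set 4, 13036 in both shTMEM45A sets, 910 between them and 15066 between targets, and 8 lists passed for TMEM45A; BOLA2B, SERF1B and UBL7-AS1 no longer passed between the sets. The 12 same-numbered pairs with set 4 had correlations from -0.042 to 0.024. Depth limits genes under 0.218 CPM.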

Other observations

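All weighing of scalings, labels, table, knockdown and cell line below rests on tests chosen after the result was seen; the tests of transcript length and of other splits were written before their values were computed, though the limit to genes with a mean log2 CPM of at least 2 was set later. Transcripts of the mitochondrial genome, 13 protein-coding genes read from shared precursors, moved apart in the shTMEM45A libraries. They were looked at after their values were seen, and whether they follow the length trend of these libraries was not tested. Against NC, 8 rose and 5 fell: MT-ND3 by 2.83 (SE 0.05), MT-CO2 by 2.29 (SE 0.03) and MT-CO3 by 1.70 (SE 0.03) rose most, and MT-ND4L changed by -1.93 (SE 0.06), MT-ND5 by -1.22 (SE 0.04) and MT-ND4 by -0.93 (SE 0.04). In the libraries labelled shSHCBP1, 3 rose and 6 fell, none by more than 0.32. Mitochondrial genes took 3.54% of counts in NC and 3.41% and 3.90% in sets 4 and 2.

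Lists that did not pass camera had adjusted p from 0.0512 to 0.736 for 17 lists in the libraries labelled shSHCBP1, and from 0.0766 to 0.953 for 19 in the shTMEM45A libraries. In the libraries labelled shSHCBP1, mitotic genes had 10 of 30 higher and 5 lower, with CENPF at 0.54 and TOP2A at -0.29, damage response genes 6 of 21 higher and 11 lower, EGFR and MAPK genes 9 of 25 higher and 3 lower (ETV4 1.28, FOS -0.74), integrated stress response genes 11 of 24 higher and 7 lower (ATF3 -0.59), and Wnt, Notch and TGF-beta targets 8 of 28 higher and 3 lower. Interferon genes had 5 of 27 higher and 2 lower, antigen presentation 2 of 15 and 6, NRF2 and ferroptosis 3 of 22 and 8, disulfidptosis genes 3 of 10 and 3, apoptosis 3 of 20 and 2, autophagy and lysosome 7 of 24 and 9, and small RNA processing 2 of 14 and 5. Epithelial adhesion genes had 2 of 20 higher and 2 lower, basal keratin genes 1 of 4 and 0, luminal breast genes 3 of 11 and 1, fibroblast markers 0 of 3 and 0, and leukocyte and endothelial markers 1 of 3 and 0. Adjusted over the list alone, these counts differed by at most 2. The balance depended on scaling: mitotic genes had 6 higher and 8 lower with RLE but 18 and 1 with total counts, and Wnt, Notch and TGF-beta targets 6 and 7 against 14 and 0, and among the 4 scalings both lists passed camera only with total counts.

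In the shTMEM45A libraries, mitotic genes had 9 of 30 higher and 19 lower (BIRC5 0.97, TOP2A -1.87), replication genes 10 of 30 and 15 (MCM2 -3.90, TYMS -2.99), p53-pathway genes 10 of 22 and 10 (BAX 1.71, XPC -2.15), integrated stress response genes 14 of 24 and 8 (NUPR1 3.48, ASNS -3.09) and chaperone genes of the endoplasmic reticulum 7 of 20 and 11 (HSPA5 -2.93, SEC61B 1.79). Antigen presentation genes had 10 of 15 higher and 3 lower, NRF2 and ferroptosis 13 of 22 and 9, EGFR and MAPK 8 of 25 and 9, Wnt, Notch and TGF-beta targets 9 of 28 and 14, apoptosis 8 of 20 and 4, autophagy and lysosome 14 of 24 and 8, and small RNA processing 4 of 14 and 9 (DICER1 -1.35). Epithelial adhesion genes had 7 of 20 higher and 10 lower, basal keratin genes 4 of 4 and 0, luminal genes 5 of 11 and 4 (KRT18 1.76), fibroblast markers 0 of 3 and 1, and leukocyte and endothelial markers 2 of 3 and 1. Median and mean differed in sign for antigen presentation, disulfidptosis, NRF2 and autophagy genes in the libraries labelled shSHCBP1, where the test went with the median. They also differed for disulfidptosis, EGFR and MAPK, apoptosis and fibroblast genes in the shTMEM45A libraries, where the test went with the mean for apoptosis and fibroblast genes and with the median for the others. EGFR and MAPK genes leaned lower in set 2 and higher in set 4, without passing in either.

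SHCBP1 was not lower in the libraries labelled shSHCBP1. Scaling argues against itself as the cause: the lowest log2 change over both sets and 4 scalings was -0.0711, far from the -0.5 that a knockdown hidden by scaling would need. The highest change of a set against NC was 0.10, below 0.5 by more than its SE of 0.07. This argues against a swap of labels with NC only if the hairpins lowered SHCBP1 by at least 0.5. Hairpins that failed would give the same values under swapped labels, so the test cannot exclude a swap. SHCBP1 stood at 41.3 to 67.4 CPM over all 15 libraries, highest in the shTMEM45A sets (0.25 and 0.44 above NC on the log2 scale), and TMEM45A fell only there. These values cannot decide on an exchange of the labels of the targets. Most genes differed between the shTMEM45A libraries and NC, which stand in separate tables, and 7402 and 7580 of 19051 were lower in sets 4 and 2. Whether the hairpins failed, acted on protein, or the libraries are not those the labels describe stays open, and so does whether these libraries carry a loss of SHCBP1.

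Most genes differed between the shTMEM45A libraries and NC, many with larger changes than TMEM45A itself. Subtracting the trend on transcript length lowered the SD of log2 changes over genes by 13%, from 1.03 to 0.897. A fall of more than 50% was set as the mark, so length as measured left most of the spread. The lengths are those of mouse genes and the trend may be blurred by that, so a larger share for length is not excluded. A batch between the deposited tables and the knockdown cannot be told apart, because the shTMEM45A libraries have no control in their table; they differed from the libraries labelled shSHCBP1 in 15105 genes, and TMEM45A did not differ between the sets (adjusted p = 0.556), so no dose could be read. For the interferon genes, the median change less the length trend was 0.82 (bootstrap SE 0.87) against a mark of 0.81, which decides nothing, although 8 of 23 members lay above 2.97, the highest value of the trend. Their median difference from the libraries labelled shSHCBP1 was 1.37. A batch or the knockdown could give this, and the design cannot weigh one against the other. Other sources were not tested.

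The cells may be another cell line than the label names. Levels in this paragraph are CPM without TMM scaling, unlike those above. Of 23 genes listed as typical of MDA-MB-468, 6 reached an average of 5 CPM and 13 stayed under 1: KRT5, KRT16 and KRT23 had 0 counts in all 15 libraries, and EGFR, which MDA-MB-468 is known to carry amplified, averaged 13.3 CPM. SMAD4, known to be deleted in MDA-MB-468, averaged 29.8 CPM, while 8 of 10 genes listed for HEK293-type cells reached 5 CPM, among them NEFM (256.7 in NC against 93.3 and 65.3 in shTMEM45A sets 4 and 2), IRS4 (272.6 against 28.4 and 16.4), NEFL (177.3 against 59.7 and 49.4) and LIN28B (36.8 against 20.7 and 21.4). Depth does not account for this, since 3 counts are seen at 0.218 CPM or less in every library, and neither does a mixture with a sizeable share of MDA-MB-468, as the highest library median of its markers was 1.70 CPM. The HEK293 identity is a hypothesis from genes that neuronal cells also express, no gene stood on both lists, and a biological explanation was not tested.

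Other splits of the same libraries were refitted on the groups concerned. For genes changed the same way in both sets against SHCBP1, 1 of 100 splits was as large as the real one, with 5292 genes against 4978 in the highest other, which kept NC whole and mixed the sets; splits that broke up NC gave at most 1. For both shTMEM45A sets it was 1 of 100, with 12387 against 12332, again with NC whole, and 0 where NC was broken up. Between targets it was 1 of 100, with 14675 against 0. No other split among the 100 reached these 3 counts. Splits that broke up NC or mixed the targets merged unlike groups, which raises the spread, so their low counts decide little. With NC whole, mixing the sets gave nearly the real count, so the counts say little about agreement between hairpins. The libraries of a group may be technical, so these splits cannot exclude chance between cultures or tables. For lists, chance is not excluded in the libraries labelled shSHCBP1, where 9 of 100 splits gave at least the real 10 lists and the highest gave 12. In the shTMEM45A libraries 1 of 100 did, with 9 lists against 8. For each hairpin set against NC only 10 splits exist, too few for a share under 0.05: the real groupings gave 5755 and 8165 genes for shSHCBP1_1 and shSHCBP1_2 and 14119 and 13749 for shTMEM45A sets 4 and 2, and the highest other split gave 0 in each.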
